A study of Cunninghamia lanceolata with 2 samples.

How the data were processed

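RNA sequencing of Chinese fir roots was analysed from 2 libraries, 1 from low-nitrogen plants (LN) and 1 from nitrogen-sufficient plants (CK), grouped by the nitrogen concentration in the sample labels. Per the labels, poly(A) RNA was selected, fragmented and sequenced as paired-end reads on an Illumina instrument. The number of plants behind each library, the assembler, the aligner, the counting tool and their versions are not given in the sources used here. No genome was used, and genes were identified by the unigene IDs and annotation of the table.

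The authors deposited 1 table of 32814 unigenes with estimated counts and RPKM for both libraries, log2 fold changes, p-values and FDR values, and a second copy with fewer columns. The counts of that copy are headed NN, which matches no sample label, yet equal the LN counts, and the copy was used only for this comparison. The estimated counts are deposited without normalization per the file headers and values: 57.3% of LN counts and 67.3% of CK counts are whole numbers. They sum to 25500994 in LN and 17848911 in CK. The authors' RPKM values are scaled to the effective length and to the reads assigned to unigenes, as the counts and RPKM of the table show. The effective length behind RPKM can differ between the libraries, so a ratio of RPKM and a ratio of read rates can differ for the same unigene. The deposited log2 fold change equals the log2 ratio of the RPKM values and is infinite for 1716 unigenes with a value of 0. The deposited p-value comes from a test that is not named, the FDR is its Benjamini-Hochberg adjustment, and the deposited effective length is in bases.

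Without replicates no test of the nitrogen effect was made. The main quantity was the log2 ratio of LN over CK on RPKM with a pseudocount of 1, for unigenes with a mean of at least 1 RPKM, which left out 318. Unigenes were counted as higher or lower at a 2-fold difference on that scale, which understates differences of weakly expressed unigenes. Folds printed with an interval are ratios of read rates (estimated counts over the library total) with exact 95% intervals, which cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Where a library had 0 reads, a nominal lower bound was computed against a floor of 3 reads in that library. It can exceed the lower limit of the exact interval. That floor is 0.118 CPM (counts scaled to the library total) in LN and 0.168 in CK.

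Gene lists were written as text patterns before the data were examined. They were matched to the KEGG ortholog description, or to the GO text of unigenes without a description. Swiss-Prot descriptions were not used here. A list entered with at least 5 members. Its median log2 ratio was placed among 10000 random lists of the same size, drawn from the 12999 annotated unigenes past the filter and matched on mean RPKM in 20 bins. The percentile describes these 2 libraries and is not a p-value. The strigolactone list had 1 member and the cytosolic ribosome pattern matched 0 unigenes, so neither entered. Further lists were added after the data were seen: cytosolic ribosomal proteins in KEGG wording, beta-1,3-glucanases, EREBP-like factors, plant MYB proteins, translation elongation factors, tubulin and actin, and fungal cell structures by GO term. The beta-1,3-glucanase list and the fungal GO list were written after some of their extreme members had been seen. A scan over KEGG pathways with at least 10 members was also added.

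The unigenes to name were set by a rule fixed before the data were examined. It takes the 10 annotated unigenes with the largest and the 10 with the smallest log2 ratio among those with at least 10 RPKM in the higher library. For each list it also takes the member with the highest mean and the 2 members with the largest and the 2 with the smallest ratio among those reaching 5 RPKM. This gave 162 unigenes, of which a part is described. For unigenes without annotation, the 2 extremes in each direction are given. KEGG descriptions name an ortholog group and can carry the name of an animal or microbial protein. Near-identical family members and alleles can share reads or be assembled apart, so values of single members of large families are uncertain.

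The scripts were tested on simulated counts drawn at the depths of the 2 libraries before use. Changed unigenes were drawn from those with a mean of at least 5 RPKM. Of 200 changed 2.5-fold, 97% of the higher and 83% of the lower ones were recovered at the 2-fold limit. Of unchanged unigenes 0.959% were called, and 4-fold changes were recovered at 100% and 97%. Recovery below a mean of 5 RPKM, where 15019 of the 32496 tested unigenes lie, was not simulated. The simulation covers counting error and not the variation between plants. In the simulation, 6 of 100 unshifted lists lay outside the central 95% of random lists, and 96.8% of intervals held the simulated ratio.

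Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter or a mean of at least 10 RPKM, rescaling to a median log2 ratio of 0 or by trimmed means, and a 4-fold limit. Summed list values, 1 unigene per description, other detection limits and a p-value threshold of 0.01 in the authors' deposited table were also among them. CPM in place of RPKM, KEGG descriptions only, removal of accidental pattern matches, removal of unigenes with 3 or fewer reads, 3 or fewer reads as the limit of detection, the defence list without its 5 most abundant members, and an FDR threshold for the authors' deposited table were added later. Alternatives that need replicates did not apply. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.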

Results

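Chinese fir (Cunninghamia lanceolata) is a conifer grown for timber. Plantlets were cultured for 1 month in diluted nutrient solution, and were then kept for 4 months either with nitrogen at 5.03 mM (nitrogen-sufficient, CK) or with the nitrogen of distilled water alone, below 0.01 mM (low nitrogen, LN). Root poly(A) RNA of each treatment was sequenced as 1 library, so the comparison has no replicates. Library identity follows the column headers of the deposited table, and a reduced copy of it heads the LN counts as NN, a label not explained, so every direction below rests on the headers of the full table. The deposited table lists 32814 unigenes, the gene-level units of a transcriptome assembly. The LN library holds 25500994 estimated reads, with a median of 92 per unigene, and the CK library 17848911, with a median of 53. A KEGG ortholog description is given for 8165 unigenes, Gene Ontology (GO) text alone for 4929, and no annotation for 19720. Differences are given as "higher in LN" or "lower in LN" between these 2 libraries. No p-value for the effect of nitrogen can be had from them, and every interval is a 95% interval that covers counting error only.

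The question was which root transcripts differ between plants starved of nitrogen and plants supplied with it. Transcripts of a stearoyl-CoA desaturase, 2 ammonium transporters and a peptide and nitrate transporter family member were close to 0 in CK and at 53.3 RPKM (reads scaled to transcript length and library total) or more in LN. Whether these transcripts near 0 in CK come from the plant or from another organism was not determined. Abundant transcripts for a glucan endo-1,3-beta-D-glucosidase, a chitinase, a beta-glucosidase and ferredoxin-nitrite reductase were far lower in LN. As groups, ammonium transporters and phosphate and sulphate genes stood higher in LN, and defence proteins (mostly chitinases), aquaporins, cell wall enzymes and cell cycle genes stood lower. The higher phosphate and sulphate members were mostly phosphate transporters of the PHS family, a subset not fixed in advance. Of the higher groups, 4 of 7 ammonium transporters and 4 of 15 of these phosphate transporters had 3 or fewer reads in CK, as had 87 of 226 cytosolic ribosomal proteins, and a fungal or bacterial list was higher too (median 3.09). Of 32496 unigenes with a mean of at least 1 RPKM, 4842 (14.9%) were at least 2-fold higher in LN and 2821 (8.68%) at least 2-fold lower, on the log2(RPKM + 1) scale. The other 24833 lay within 2-fold. Without unigenes that had 3 or fewer reads in either library, the counts were 2576 higher and 2251 lower. Of unigenes with a mean of at least 20 RPKM, 7.69% were higher and 6.95% lower. The median log2 ratio of LN over CK was 0.13 over all tested unigenes, and scaling by trimmed means shifted the ratios by 0.11. Across unigenes, which are not independent replicates, the libraries had a Spearman correlation of 0.720 and a Pearson correlation of 0.793.

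**Figure D1:**
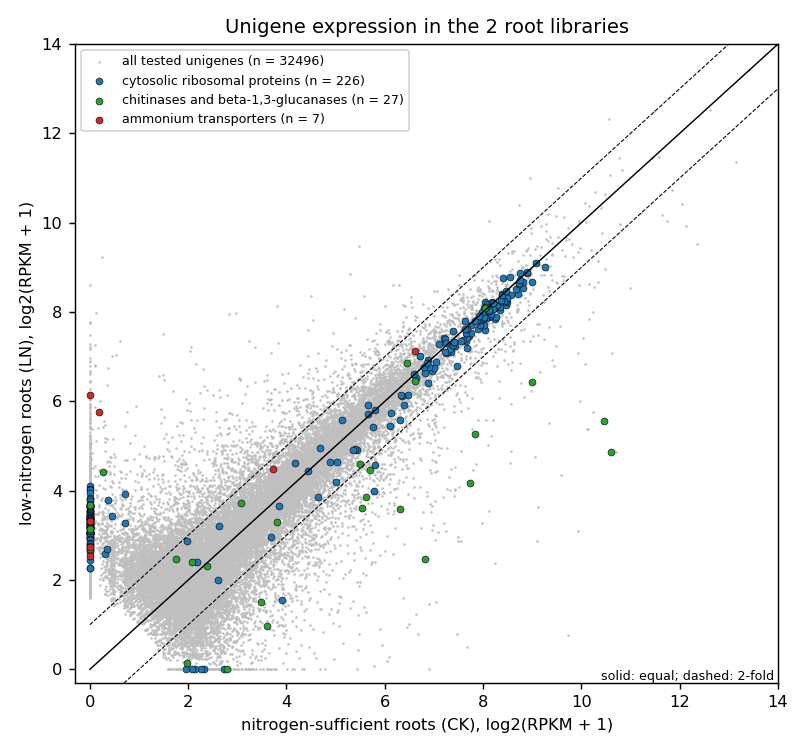
Expression of 32496 unigenes in CK (x axis) and LN (y axis) roots as log2(RPKM + 1), 1 point per unigene. The solid line marks equal values and the dashed lines a 2-fold difference. Several chitinases and beta-1,3-glucanases (green) lie below the lower dashed line, and 5 of 7 ammonium transporters (red) have 0.14 RPKM or less in CK. Most cytosolic ribosomal proteins (blue) lie along the solid line, and 87 have 3 or fewer reads in CK.

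Among annotated unigenes reaching 10 RPKM, the 10 with the smallest ratio began with a beta-glucosidase (comp18357_c0), at 7.56 RPKM in LN against 974 in CK, or 129-fold lower (interval 116 to 143). Nicotianamine synthase (comp21745_c0), which makes a metal chelator, was 234-fold lower (158 to 362), at 0.72 against 177 RPKM. The glucan endo-1,3-beta-D-glucosidase comp26227_c0 had 28.4 RPKM in LN and 1549 in CK, and the chitinase comp26600_c0 had 46.1 and 1413. Both belong to enzyme families that act on fungal cell wall polymers. Both aminocyclopropanecarboxylate oxidases in this set, comp25697_c0 and comp21662_c0, catalyse the last step of ethylene synthesis. Their values were 1.01 and 2.03 RPKM in LN against 89.5 and 82.1 in CK. The others were a flavonol synthase (comp31858_c0, 0.14 against 65.1 RPKM), an N1-acetylpolyamine oxidase (comp10040_c0, 0.06 against 54.0), a peroxidase (comp20256_c0, 0.93 against 86.2) and comp5895_c0 (6.36 against 185), whose KEGG description names a mixed-lineage leukemia protein.

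The 10 with the largest ratio all had 5 or fewer reads in CK. RNA of another organism may account for part of the unigenes near 0 in CK, and the origin of these 10 was not determined. A delta-9 stearoyl-CoA desaturase (comp10090_c0), which introduces a double bond into fatty acids, had 147 RPKM in LN and 0 reads in CK, and so was at least 1250-fold higher. An acyl carrier protein (comp23701_c0) had 109 against 0.08 RPKM, and a phospholipase A2 (comp23451_c0) had 131 against 0.44. With 0 reads in CK stood a subtilisin protease (comp26587_c0, 64.3 RPKM in LN), an NAD-dependent glycerol-3-phosphate dehydrogenase (comp22791_c0, 58.7), a peroxiredoxin (comp18285_c0, 57.8), a nucleolin (comp18015_c0, 57.2) and a phosphoadenosine phosphosulfate reductase (comp32393_c0, 56.5). The remaining members were the ammonium transporter comp17440_c0 and the oligopeptide transporter comp26973_c0, described with their groups. Of unigenes with no annotation, the extremes were comp21476_c0 (391 RPKM in LN, 0 reads in CK), comp26258_c0 (600 against 0.18 RPKM), comp27213_c0 (0.70 against 846) and comp28140_c0 (0.42 against 203).

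All 7 ammonium transporters were higher in LN, and 5 by at least 2-fold. The unigene comp17440_c0 had 69.9 RPKM in LN and 0 reads in CK. Against the floor of 3 reads it was 674-fold higher, and its exact interval began at 548. The unigene comp16516_c0 had 53.3 against 0.14 RPKM, 438-fold higher (171 to 1609). The most abundant member, comp25882_c0, had 140 against 96.9 RPKM, 1.39-fold higher (1.32 to 1.46). The median log2 ratio of the group was 2.74, at percentile 100 of 10000 random lists matched on expression, and 3.26 with unigenes at 0 reads set to their bound. It was 5.85 with a pseudocount of 0.1, 1.38 on CPM (counts scaled to the library total alone) and 1.47 for summed RPKM. Of the 7, 4 had 3 or fewer reads in CK, and 3 of those 4 had below 10 RPKM in LN. The median of 2.74 is the value of 1 of those 3, comp139553_c0, with 29 reads in LN and 0 in CK. Without unigenes of 3 or fewer reads the list keeps 3 members, too few for it to be placed among random lists. The nitrate transport list had 5 members and a median of 0.26 (percentile 72.0), within the range of random lists, and 2 of its members were matched through a sulfonate, nitrate and taurine system. Its nitrate/nitrite transporters comp25897_c0 and comp26314_c0 had 69.9 and 133 RPKM in LN against 26.6 and 81.4 in CK, 2.63-fold (2.45 to 2.82) and 1.64-fold (1.57 to 1.71) higher. The nitrate/nitrite transporter comp24051_c0 had 5.04 against 5.76 RPKM, a difference within counting error.

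The nitrate reduction and ammonium assimilation list also holds accidental matches. Of its 71 members, 15 were at least 2-fold higher and 10 at least 2-fold lower (median 0.15, percentile 83.1). Ferredoxin-nitrite reductase (comp14490_c0), which reduces nitrite to ammonium in plastids, was 7.89-fold lower (7.56 to 8.22), at 36.3 RPKM in LN and 286 in CK. Nitrate reductase comp16880_c0 was 1.51-fold lower (1.46 to 1.56), at 80.9 against 123.2 RPKM. Among other members, chosen after their values were seen, the NADH-type glutamate synthase comp21774_c0 had 23.3 against 62.6 RPKM and the asparagine synthase comp21783_c0 had 25.7 against 104. Their counterparts were closer, with 35.3 against 39.7 RPKM for the ferredoxin-type glutamate synthase comp7797_c0 and 38.9 against 33.6 for the asparagine synthase comp14701_c0. A glutamate dehydrogenase (comp18314_c0) had 0.99 against 13.9 RPKM, and the more abundant comp25231_c0 had 78.3 against 79.9. The most abundant glutamine synthetase, comp19654_c0, the entry enzyme of ammonium assimilation, had 788 RPKM in LN and 863 in CK. Of the 71 members, 7 had 3 or fewer reads in CK, among them the glutamine synthetase comp17457_c0 and comp3927_c0, at 6.74 and 5.18 RPKM in LN. The latter is a nitrate reductase in KEGG wording only, and its GO text names cytochrome-b5 reductase activity. The list pattern also matched other enzymes by their KEGG wording, among them laccase-type oxidases described as NO-forming nitrite reductase. Without the matches recognised as accidental, 42 members had a median of 0.0058, with 6 higher and 8 lower. Some of the 42 still rest on KEGG wording alone. The carbamoyl-phosphate synthase large subunit comp6328_c0 has GO text on petal development, and the glutamine synthetase comp20790_c0 on phosphatase activity. Of the 6 higher, 4 had 3 or fewer reads in CK. The others were the carbamoyl-phosphate synthases comp11580_c0 and comp64913_c0, without GO text. None of the 8 lower had 3 or fewer reads in LN. Summed RPKM of the 71 members gave -0.27. The KEGG pathway of nitrogen metabolism, scanned after the data were seen, had 17 of 66 members higher and 14 lower (median -0.019, percentile 13.4).

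**Figure D2:**
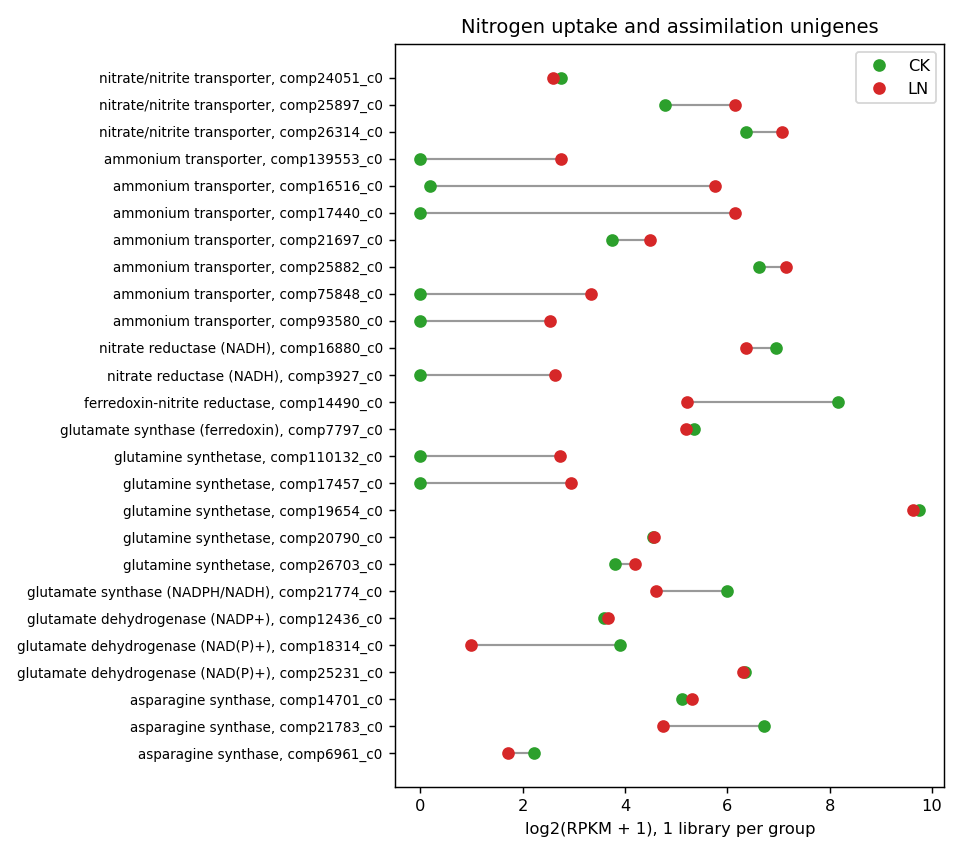
Nitrogen uptake and assimilation unigenes, 1 row per unigene, as log2(RPKM + 1) in CK (green) and LN (red), 1 library each. The ferredoxin-nitrite reductase comp14490_c0 lies lower in LN (36.3 against 286 RPKM), and the ammonium transporters comp17440_c0 and comp16516_c0 lie near 0 in CK.

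Amino acid, peptide and urea transporters were higher as a group, with 22 of 73 members at least 2-fold higher, 12 lower and a median of 0.47 (percentile 100). Of these, 61 were proton-dependent oligopeptide transporters, the family that includes plant nitrate and peptide transporters, with 17 higher and 9 lower. The member comp26973_c0 had 63.0 RPKM in LN and 0.16 in CK, 405-fold higher (158 to 1489), and comp27303_c0, the most abundant, had 146 against 255. The list median was 0.16 with 1 unigene per description, which leaves 1 oligopeptide transporter beside members matched by GO text (median 0.17 over all 12). It was 0.30 without unigenes of 3 or fewer reads, and 10 members had 3 or fewer reads in CK. Phosphate and sulphate transport and starvation genes had 12 of 42 members higher and 1 lower (median 0.46, percentile 99.99). Among them, 9 of the 15 inorganic phosphate transporters of the PHS family were higher and 1 lower. The median of these 15 was 2.81, with summed values of 465 RPKM in LN and 198 in CK. This subset was not fixed in advance and was not placed among random lists. The 15 members matched by GO text had 1 higher (median 0.10), and no member had a sulphate transporter as its KEGG description. The phosphate transporter comp24497_c0 had 173 against 124 RPKM and comp21878_c0 had 16.0 RPKM against 0 reads. Of the 42 members, 5 had 3 or fewer reads in CK, and the median was 0.19 with 1 unigene per description.

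Aquaporins, which conduct water across membranes, were lower in LN: 10 of 28 were at least 2-fold lower and 2 higher, with a median of -0.82 (percentile 0). Of the 10 tonoplast (TIP) forms, 8 were lower, with a median of -1.34 and a sum of 902 RPKM in LN against 2055 in CK. The TIP aquaporin comp21192_c0 had 86.4 against 320 RPKM. The 10 plasma membrane (PIP) forms had a median of -0.63, and comp5655_c0, the most abundant, had 1193 against 2355 RPKM. Both aquaporins that were at least 2-fold higher had 3 or fewer reads in CK. Potassium, iron and metal transport genes had 1 member higher and 6 lower of 31 (median -0.035, percentile 24.1). The higher one was ferritin (comp23566_c0), an iron storage protein, at 325 against 46.7 RPKM, 6.97-fold higher (6.58 to 7.38).

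Defence and pathogenesis-related genes had 15 of 30 members at least 2-fold lower and 7 higher, with a median of -1.001 (percentile 0). By KEGG description 20 members were chitinases, of which 9 were lower and 4 higher, and their summed values were 651 RPKM in LN and 2858 in CK. The chitinase comp26600_c0 was 30.8-fold lower (29.3 to 32.4), and comp23644_c0 had 17.0 against 211 RPKM. In the opposite direction, the chitinases comp18688_c0 and comp14381_c0 had 11.9 and 20.3 RPKM in LN with 0 and 2 reads in CK. In all, 6 of the 30 members had 3 or fewer reads in CK, and without unigenes of 3 or fewer reads in either library the median was -1.46. Summed RPKM of the list gave -2.03, and the median without its 5 most abundant members was -0.35. The 6 beta-1,3-glucanases, a list written after an extreme member had been seen and so no independent evidence, had 4 members lower and none higher (median -1.50, percentile 0.020). The KEGG pathway of plant-pathogen interaction, scanned after the data were seen, leaned the other way, with 10 of 63 members higher and 6 lower (median 0.18, percentile 92.2), within the range of random lists.

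Redox and detoxification genes had 31 of 193 members higher and 41 lower (median 0.023, percentile 20.3), and their summed RPKM gave -0.47. Of 79 peroxidases, 36 were lower and 5 higher, with a median of -0.72 and summed values of 2108 RPKM in LN and 5049 in CK. Catalase comp18506_c0, which breaks down hydrogen peroxide, had 1046 against 3431 RPKM, 3.28-fold lower (3.25 to 3.32). Superoxide dismutases went the other way: 5 of 8 of the Fe-Mn family and 3 of 5 of the Cu/Zn family were higher and none was lower. All 5 of those Fe-Mn forms and 1 Cu/Zn form had 3 or fewer reads in CK, as did 21 of the 193 list members. A glutathione S-transferase (comp22459_c0) had 41.9 RPKM in LN and 0 reads in CK.

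Cell wall genes had 64 of 192 members at least 2-fold lower and 21 higher, with a median of -0.40 (percentile 0). Endoglucanases were lower in 15 of 22 unigenes (median -1.45), xyloglucan:xyloglucosyl transferases, which rejoin xyloglucan chains, in 14 of 30 (-0.88), and pectinesterases in 17 of 41 (-0.64). Cellulose synthase A did not share this, with 7 of 34 higher and 5 lower (median 0.093), and the 25 members matched by GO text had 5 higher and 3 lower (0.12). The pectinesterase comp29730_c0 had 3.39 against 35.7 RPKM. The most abundant member, the xyloglucan:xyloglucosyl transferase comp18426_c0, had 448 RPKM in LN and 289 in CK. Of the members, 7 had 3 or fewer reads in CK and 8 in LN. The median was -0.17 for members with a mean of at least 10 RPKM. With 1 unigene per description it was 0.092, but this leaves each described family 1 member, so that members matched by GO text weigh more.

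Flavonoid and anthocyanin genes had 25 of 141 members lower and 17 higher (median -0.098, percentile 0.125), and summed RPKM gave -0.45. Chalcone synthase, the first committed enzyme of the pathway, was lower in 4 of 5 unigenes (median -1.63), and comp26086_c0 had 378 RPKM in LN against 1218 in CK, 3.22-fold lower (3.13 to 3.33). Flavonol synthase was higher in 7 of 13 unigenes and lower in 3 (median 1.31), and leucoanthocyanidin dioxygenase was higher in 2 of 7 and lower in 1 (0.43). In this list, 3 members had 3 or fewer reads in CK and 5 in LN. The KEGG pathway of flavonoid biosynthesis, scanned after the data were seen, had 19 of 87 members higher and 20 lower (median 0.025, percentile 28.7), within the range of random lists, and that of flavone and flavonol biosynthesis had 4 of 35 higher and 4 lower (-0.15, 2.23), below it. Phenylpropanoid and lignin genes had 19 of 90 members higher and 10 lower (median 0.15, percentile 89.2), and 5 had 3 or fewer reads in CK. The KEGG pathway of phenylpropanoid biosynthesis, a broader set scanned after the data were seen, stood lower (median -0.26, percentile 0). It had 26 of 213 members higher and 64 lower. How far these members also belong to other lists, such as the peroxidases, was not examined. Caffeoyl-CoA O-methyltransferase comp27096_c0, an enzyme of lignin precursor synthesis, had 1336 against 425 RPKM, 3.15-fold higher (3.08 to 3.22), and cinnamoyl-CoA reductase comp19489_c0 had 192 against 20.6. Phenylalanine ammonia-lyase comp26210_c0, the entry enzyme of the pathway, had 21.3 against 80.1 RPKM. Terpenoid genes had 1 member higher and 4 lower of 32 (median -0.11, percentile 4.42).

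Cell cycle and chromatin replication genes had 50 of 224 members lower and 16 higher, with a median of -0.23 (percentile 0). Kinesin family member 15 was lower in 7 of 13 unigenes (median -1.21), the kinase subunit CKS1 in 3 of 4 (-1.17) and proliferating cell nuclear antigen in 2 of 3 (-1.51), and none of these was higher. Histone H2A went both ways, with 4 of 20 higher and 3 lower (median 0.17). Its unigenes comp12774_c0 and comp15915_c0 had 2.53 and 2.04 RPKM in LN against 19.8 and 16.2 in CK. The histones comp5308_c0 (H2B) and comp23758_c0 (H3) had 19.7 and 21.9 RPKM in LN and 0 reads in CK, and 15 members of the list had 3 or fewer reads in CK. The most abundant member, histone H3 comp24077_c0, had 562 against 514 RPKM. The median was -0.12 with 1 unigene per description and -0.13 for members with a mean of at least 10 RPKM.

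Sucrose and starch genes had 11 of 52 members lower and 4 higher (median -0.20, percentile 0.040). This direction turned with 1 unigene per description (0.25), with a mean of at least 10 RPKM (0.054) and for summed RPKM (0.032). The KEGG pathway of starch and sucrose metabolism, a larger set scanned after the data were seen, stood lower (median -0.35, percentile 0). It had 27 of 271 members higher and 76 lower. How far these members also belong to other lists, such as cell wall genes, was not examined. The pathway is thus no separate evidence on sucrose and starch genes. The beta-amylase comp20894_c0, which degrades starch, had 71.0 against 7.97 RPKM, 8.91-fold higher (7.98 to 9.98). Glycolysis, citrate cycle and respiration genes had 11 of 86 members higher and 3 lower (median -0.013, percentile 13.6), and 10 had 3 or fewer reads in CK. In the scan of KEGG pathways, glycolysis and gluconeogenesis (22 and 13 of 129, 0.055, percentile 41.2) lay within the range of random lists, and the citrate cycle (4 and 3 of 47, -0.15, percentile 0.6) and oxidative phosphorylation (29 and 6 of 141, -0.071, 0.67) lay below it, the latter with 25 members at 3 or fewer reads in CK. Proteolysis genes had 51 of 316 members higher and 17 lower (median 0.14, percentile 97.6), and 35 had 3 or fewer reads in CK. Without unigenes of 3 or fewer reads the proteolysis median was 0.065. After setting the median ratio of unigenes with a mean of at least 10 RPKM to 0 it was 0.049, but this rescaling lowers the random lists as well. With KEGG descriptions only, the proteolysis median was 0.086 (percentile 64.8), within the range of random lists. Autophagy and senescence genes (4 higher and 1 lower of 40, median 0.16, percentile 83.2), heat shock proteins and chaperones (23 and 11 of 112, 0.085, 60.2) and dehydration stress genes (0 and 0 of 19, -0.055, 17.9) lay within the range of random lists. Of the chaperones, 14 had 3 or fewer reads in CK.

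The hormone lists rest mostly on GO text, which records processes assigned to related proteins. Auxin genes had 24 of 148 members higher and 10 lower (median 0.27, percentile 100), 144 of them matched by GO text, so that KEGG descriptions alone left too few members, and summed RPKM gave 0.42. Of these, comp26831_c0, annotated as an indole-3-acetic acid amido synthetase, had 26.0 against 0.32 RPKM. Jasmonate and salicylate genes had 31 of 130 members higher and 10 lower (median 0.39, percentile 100). Of them, 101 were matched by GO text, and the 29 with a matching KEGG description had a median of 0.13 (percentile 72.1), within the range of random lists. Summed RPKM of the list gave 0.20. Lipoxygenase, which starts jasmonate synthesis from fatty acids, was lower in 6 of 18 unigenes and higher in 3, and comp26770_c0 had 23.6 against 374 RPKM, 15.8-fold lower (15.1 to 16.6). Abscisic acid genes had 13 of 87 members higher and 3 lower (median 0.21, percentile 98.2), and the 10 with a matching KEGG description had a median of 0.085 (percentile 45.1), within the range of random lists. In these lists, 7 auxin, 8 jasmonate and salicylate and 5 abscisic acid members had 3 or fewer reads in CK.

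Ethylene genes (11 higher and 8 lower of 76, median 0.13, percentile 77.6), cytokinin genes (10 and 5 of 57, 0.17, 87.5) and gibberellin and brassinosteroid genes (5 and 6 of 48, -0.036, 13.8) lay within the range of random lists. With KEGG descriptions only, the 15 cytokinin members lay above that range (median 0.57, percentile 99.4). The 13 such gibberellin and brassinosteroid members stayed inside it, with a median of 0.34 (percentile 96.3). Within the ethylene list, aminocyclopropanecarboxylate oxidases differed in direction: comp14611_c0 had 95.9 against 1.79 RPKM, 53.7-fold higher (39.0 to 76.0), while comp25697_c0 was 88.7-fold lower (63.3 to 128). In the cytokinin list the most abundant member, the cytokinin trans-hydroxylase comp26961_c0, had 322 against 91.6 RPKM. The ent-kaurene oxidase comp25073_c0 of gibberellin synthesis had 95.5 against 11.1 RPKM, 8.39-fold higher (7.52 to 9.39). The nitrogen signalling list is void: its 51 members, with 0 higher and 4 lower (median -0.066, percentile 5.37), were mostly cell division cycle proteins matched by wording.

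**Figure D3:**
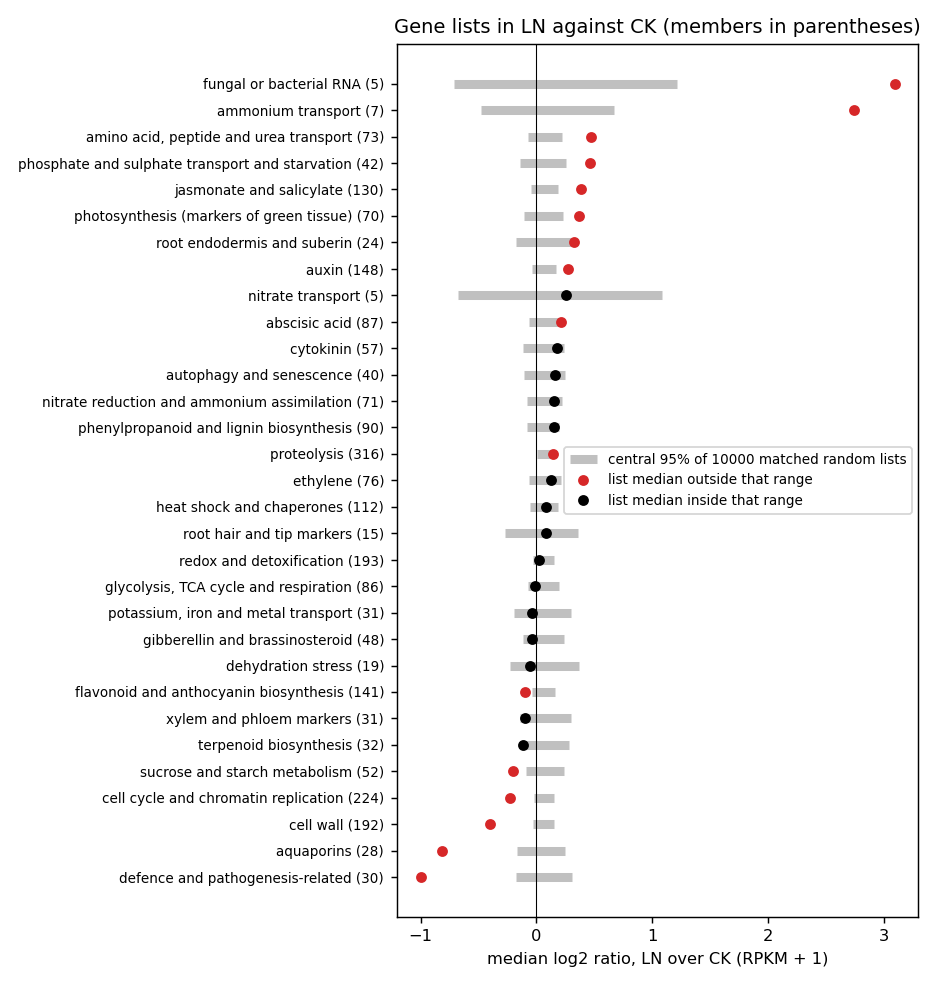
Median log2 ratio of LN over CK for 31 gene lists, with the number of members in parentheses. Points are list medians and grey bars the central 95% of 10000 random lists matched on expression. Red points lie outside the bar. Ammonium transport (2.74) lies at the upper end and defence and pathogenesis-related genes (-1.001) at the lower end, apart from the 5 unigenes of the fungal or bacterial list (3.09).

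Markers of other tissues and organisms were compared in the same way. Photosynthesis genes, markers of green tissue, had 23 of 70 members higher and 9 lower (median 0.37, percentile 99.96), with 5 at 3 or fewer reads in CK. Their summed RPKM gave -0.16, with 83.6 against 434 RPKM for the photosystem II protein PsbA (comp24767_c0). Endodermis and suberin genes had 3 of 24 members higher and 2 lower (median 0.32, percentile 98.5). The 10 members with a matching KEGG description, acylglycerol-phosphate acyltransferases and feruloyl esterases matched by accident, had a median of 0.17 (percentile 74.6), within the range of random lists. Without them the 14 members matched by GO text had a median of 0.47 (percentile 98.96). Root hair and tip markers (2 and 2 of 15, 0.084, percentile 57.3) and xylem and phloem markers (3 and 2 of 31, -0.10, 5.25) lay within the range of random lists. The fungal or bacterial list had 4 of 5 members higher and none lower (median 3.09, percentile 99.85, and 3.10 with unigenes at 0 reads set to their bound). Its most abundant member, comp22997_c0, had 35.6 against 27.7 RPKM, and summed RPKM gave 1.43. Of the 34 lists fixed before the data were examined, 32 had at least 5 members. Of these, 6 lay below percentile 2.5 and 10 above 97.5, where 1.6 would be expected with members drawn at random. Lists hold gene families whose members may vary together, so this is no test.

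Detection in 1 library alone was uneven. In CK, 1451 unigenes had 0 reads and at least 1 RPKM in LN, against 166 in the opposite direction, and at 5 RPKM or more the counts were 1097 and 57. A count of 0 allows up to 0.168 CPM in CK and 0.118 in LN. The LN-only unigenes held 0.795% of LN reads, and 669 of them were annotated. With 3 or fewer reads in place of 0, the counts were 2714 in LN and 715 in CK, and the 2714 held 1.07% of LN reads (Clopper-Pearson interval 1.07 to 1.08). Cytosolic ribosomal proteins, a list added after the data were seen, had 90 of 226 members higher and 9 lower (median 0.052, percentile 49.1). In this list, 87 members had 3 or fewer reads in CK, at 3.82 to 16.1 RPKM in LN, and 6 had 3 or fewer reads in LN.

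In the authors' deposited table, 4300 unigenes were marked significant, 2970 higher and 1330 lower in LN, at an unadjusted p below 0.05 and a 2-fold difference. Of those 4300, 2217 had an FDR of 0.05 or more in the authors' deposited table, with a largest value of 0.298. With an FDR below 0.05 in place of p, the authors' deposited table gave 1350 higher and 733 lower. As the authors' values also compare 1 library with 1 library, their p-values do not refer to the nitrogen treatments. For 99.98% of unigenes compared, they match a chi-square test on RPKM handled as counts, within 1% of log10 p. They therefore do not measure counting error between these libraries either.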

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

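No paired analysis was possible because each group has 1 library, and for the same reason leaving out a replicate was not possible, no other split of the samples exists, and alternatives that need replicates were not run. The alternatives with CPM, KEGG descriptions only, without accidental matches, without unigenes of 3 or fewer reads, with 3 or fewer reads as the limit of detection, with an FDR threshold and without the 5 most abundant defence members were chosen after seeing the data. The cause of the differences below was not tested, except that a higher pseudocount, limit or filter leaves fewer unigenes by construction. Depth limits the unigenes with few reads most: 0 reads allow up to 0.168 CPM in CK.

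Unigenes at least 2-fold higher (4842) and lower (2821) were 2379 and 1018 with a pseudocount of 5, 1075 and 835 with a mean of at least 10 RPKM, 2192 and 650 at 4-fold, and 3011 and 1748 on CPM. Without unigenes of 3 or fewer reads in either library they were 2576 and 2251. With a pseudocount of 0.1 they rose to 6107 and 3645, and with the median set to 0 they were 4408 and 3086. The share of higher among differing unigenes was 63.2%, against 70.03% with a pseudocount of 5, 56.3% with a mean of at least 10 RPKM, 77.1% at 4-fold, 53.4% without unigenes of 3 or fewer reads, 58.8% with the median set to 0 and 58.4% with trimmed means. Unigenes in LN alone were 2714 and in CK alone 715 with 3 or fewer reads as the limit, and at 5 RPKM or more those in CK alone were 57. With a mean of at least 10 RPKM the Spearman correlation was 0.736 and the Pearson correlation 0.700. In the authors' deposited table, 1804 were higher and 867 lower at p below 0.01, and 1350 and 733 at an FDR below 0.05.

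With 1 unigene per description, each described family keeps 1 member, so that any members matched by GO text weigh more. List medians are given where they moved by more than the half-width of the central 95% of matched random lists. Among lists outside that range, the direction turned for cell wall with 1 unigene per description (0.092), for sucrose and starch with a mean of at least 10 RPKM (0.054), 1 unigene per description (0.25) and summed values (0.032), and for photosynthesis with summed values (-0.16). Several lists within that range, with medians near 0, also changed sign. With summed values, others were 1.47 for ammonium transport, -0.27 for nitrate reduction and ammonium assimilation, -0.45 for flavonoids, 0.42 for auxin, 0.58 for cytokinin, 0.20 for jasmonate and salicylate, -2.03 for defence, -0.47 for redox, -0.13 for cell cycle, -0.18 for glycolysis and 1.43 for fungal or bacterial RNA. With 1 unigene per description they were -0.080 for nitrate reduction and ammonium assimilation, 0.16 for amino acid, peptide and urea transport, 0.24 for the void nitrogen signalling list, 0.19 for phosphate and sulphate, -1.46 for defence, -0.062 for heat shock and -0.12 for cell cycle. With a mean of at least 10 RPKM they were 0.62 for amino acid, peptide and urea transport, -0.17 for cell wall, -0.013 for ethylene, -1.70 for defence, -0.072 for redox, -0.13 for cell cycle and -0.19 for glycolysis. KEGG descriptions only gave 0.57 for cytokinin, 0.34 for gibberellin and brassinosteroid and 0.13 for jasmonate and salicylate. Without unigenes of 3 or fewer reads, amino acid, peptide and urea transport had 0.30, proteolysis 0.065 and defence -1.46. Proteolysis had 0.049 with the median set to 0, which lowers the random lists as well. Defence had -0.35 without its 5 most abundant members. CPM gave 1.38 for ammonium transport and -0.72 for defence. A pseudocount of 0.1 gave 5.85 for ammonium transport and 4.15 for fungal or bacterial RNA. No filter on low values and removal of accidental matches moved none of the 32 and 30 lists they could be run on by that much. With KEGG descriptions only, jasmonate and salicylate, abscisic acid, endodermis and suberin, and proteolysis came inside the range of random lists and cytokinin went above it. For endodermis and suberin those descriptions were the accidental matches, and the list without them stayed above the range (0.47). Lists left with too few members were not run: ammonium transport with 1 unigene per description, a mean of at least 10 RPKM or without unigenes of 3 or fewer reads; nitrate transport with the first 2 of these or without accidental matches; aquaporins with 1 unigene per description; fungal or bacterial RNA with a mean of at least 10 RPKM, without unigenes of 3 or fewer reads or by KEGG descriptions; auxin, root hair and xylem markers by KEGG descriptions; and nitrogen signalling without accidental matches. Of 162 named unigenes, 60 moved by more than their counting error (or by 2 log2 units where a library had 0 reads) with a pseudocount of 0.1 and 38 with the median set to 0. With the median set to 0, comp26806_c0 went from 0.051 to -0.046.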

Other observations

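The pathway scan, the added lists and the tests on depth, alleles, the ammonium transporters, library scaling, the library labels, the abundant defence members left out and the deposited p-values were chosen after the results were seen. The tests on ribosomal proteins, and on the share of defence members below the overall median, were set before their values were seen.

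Among KEGG pathways with at least 10 members, 25 lay below percentile 2.5 of matched random lists and 14 above 97.5. With members drawn at random 6.15 would be expected, but pathways share members and hold gene families, so this is no test. Light-harvesting antenna proteins, which carry chlorophyll in green tissue, were higher in 10 of 16 unigenes and lower in none (median 1.22, percentile 100), and none of the 16 had 3 or fewer reads in CK. The KEGG pathway of photosynthesis had 11 of 47 higher and 10 lower (median 0.24, percentile 96.3), within the range of random lists. Sulfur metabolism was higher in 17 of 35 and lower in 1 (median 0.60), with 13 at 3 or fewer reads in CK. Diterpenoid biosynthesis, which holds gibberellin precursors, was higher in 7 of 19 and lower in 1 (median 0.61). DNA replication genes were lower in 18 of 82 and higher in none (median -0.44, percentile 0), and none had 3 or fewer reads in CK. Pentose and glucuronate interconversions, which hold pectin-degrading enzymes, were lower in 29 of 88 and higher in 9 (median -0.54). Among the added lists, tubulin and actin had 5 of 40 members higher and 6 lower (median -0.34, percentile 0.020), and 3 had 3 or fewer reads in CK. EREBP-like factors (8 higher and 17 lower of 61, median -0.041, percentile 9.86), plant MYB proteins (10 and 8 of 84, 0.11, 72.0) and translation elongation factors (12 and 7 of 33, 0.042, 40.3) lay within the range of random lists. Unigenes with GO terms of fungal cells, a list written after extreme members had been seen and so no independent evidence, were higher in 16 of 35 and lower in none (median 0.50, percentile 99.95), and 13 had 3 or fewer reads in CK.

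The first pattern is the set of unigenes with reads in LN and none in CK. For lower depth of CK, the LN abundance predicts a median of 32.2 reads in CK for them. The set was chosen by a minimum LN abundance, and all 1451 had a predicted CK count above 3 reads. A low median could thus not come out, and the test does not decide on depth as a cause. It shows only that the depth of CK left room to detect these unigenes at their LN abundance. For alleles or genotypes assembled apart, LN-only unigenes outnumber CK-only ones 19.2 times at 5 RPKM. This argues only against allele differences that act equally in both directions. The number of plants behind each library is not known, so the ratio does not decide on unequal ones. RNA of another organism in the LN library may account for part of the LN-only unigenes. Here 72 ribosomal protein orthologs had a unigene with 3 or fewer reads in CK beside another present in both libraries. In the opposite direction, 6 did. Those near 0 in CK had a median of 8.52 RPKM in LN, against 187 for those in both. Of all unigenes at 3 or fewer reads in CK, 182 lay above the highest such ribosomal protein in LN, 69 of them annotated. Translation elongation factors, also made by every cell, had 7 of 33 at 3 or fewer reads in CK and 4 in LN, tubulin and actin had 3 of 40 and none, and no sequence was at hand to name an organism. A plant nitrogen response cannot be the whole of it, because 74 ribosomal protein orthologs, made by every cell, were among unigenes near 0 in CK, yet it stays open for single unigenes: of the 4 ammonium transporters at 3 or fewer CK reads, 3 lay at 4.79 to 9.04 RPKM in LN, inside the 3.82 to 16.1 of such ribosomal proteins, and the other stood at 4.34 times their highest value, which does not decide between the plant and another organism.

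The second pattern is the lower defence list, which was first set out together with jasmonate and narrowed when the jasmonate and salicylate list came out higher. For library scaling or dilution of root RNA, unigenes with a mean of at least 10 RPKM had a median log2 ratio of 0.098, not one near -1.001. RPKM is scaled to the assigned reads of each library, so a median near -1.001 could hardly come out. The test therefore does not decide on scaling or dilution, and shows only that the defence list was lower relative to these unigenes. A few abundant unigenes as the whole cause are argued against. Without the 5 most abundant members the median was -0.35 (percentile 0.29), still below the range of random lists, although those members carried much of its size. That test, with 5 the only number tried, replaced one set in advance that came out undecided, with 66.7% of members below the median of all tested unigenes, between its limits of 50% and 70%. Nitrogen supply, named by the design, and differences between individual plants or harvests remain open and untested with 1 library per group.

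The third pattern concerns the deposited p-values. For 99.98% of 32774 unigenes, they equal a chi-square test without continuity correction on RPKM handled as counts, within 1% of log10 p. The same test on the estimated counts gave the deposited value for 0.0062% of unigenes and would mark 8952 at p below 0.05 and 2-fold. A test on RPKM takes no account of the reads behind a value. At a given fold, the p-value of such a test falls as the RPKM values rise, so the share marked depends on abundance by construction. Of 2-fold unigenes, 23.3% below a mean of 5 RPKM were marked significant, against 100% of those at 20 RPKM or more. No biological explanation was tested for this pattern.

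The fourth pattern is the direction of every difference, which depends on the labels of the libraries. Exchanged labels stay open: the fold changes had the same sign in the 2 deposited copies for 100% of unigenes whose value did not round to 0, but the reduced copy heads the LN counts as NN, and no other record of library identity was at hand.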
